A study of Mus musculus with 4 samples.

How the data were processed

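RNA from 4 sorted populations of mouse bone marrow cells was hybridised to Affymetrix arrays, with 1 array each for wild-type LSK, Fbw7-deficient LSK, wild-type MP and Fbw7-deficient MP cells. Per the labels' protocols, mice received 3 injections of polyI:C at 20 ug per g, marrow was taken 2 weeks later, marrow of 3 mice was pooled per genotype, and 20 ng of total RNA was amplified by a 2-cycle protocol and labelled with biotin. Small RNA inputs amplified in this way favour sequence near the 3' end of transcripts, so the ratio of 3' to 5' control probe sets is given for each array. All 4 samples were assigned to groups from their titles.

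The deposited values are intensity per probe set on a linear scale, summarised by RMA per the submitters' processing notes; the version, software and settings of RMA are not given in the sources used here. RMA corrects background, makes the distributions of arrays equal and summarises the probes of a probe set, so total RNA content per cell and changes shared by most genes are not seen in these values, and differences of dim genes are compressed. The deposited columns had nearly equal distributions (medians 156, 159, 157 and 155). That the scale is linear follows from their range, up to 43564. No detection calls were used here, so a low intensity is not called absent. All values were taken to log2 here before any difference was computed. A probe set's level was compared between arrays and not with that of another probe set.

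Of 45101 probe sets, 34945 name exactly 1 gene in the platform annotation used here, 932 name several and 9224 are unnamed, the 64 control probe sets included. For 34741 the symbol was looked up by gene ID in a RefSeq table of assembly GRCm38.p6, used for names and for which genes are neighbours; the other named probe sets kept the annotation's symbol. Probe sets with several genes were used for none of them. Each of the resulting 18193 genes was represented by its probe set with the highest mean log2 value over the 4 arrays; 9010 genes had more than 1. Genes whose highest array value reached the median of all values (an intensity of 157) were kept, which left 12239. Ly6a, which encodes Sca1, Trp53 and Ddx3y were to be named always but are not named by the annotation used here, so they are not analysed here.

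Fbw7-deficient was compared with wild-type LSK, Fbw7-deficient with wild-type MP, wild-type LSK with wild-type MP and Fbw7-deficient LSK with Fbw7-deficient MP, each as a difference of log2 values, and the first 2 differences were subtracted from each other. With 1 array per group no test was made and no standard error or p-value is given. The LSK and MP arrays of a genotype share a pool of mice, so an additive fit of genotype and population would leave 1 residual degree of freedom; its residual is the difference of the genotype differences, which is itself compared here, so it was not used as an error. A gene is called higher or lower at 2-fold. The comparisons that share an array also share its chance errors: the LSK genotype comparison and the wild-type LSK against MP comparison both use the wild-type LSK array. Before the data were examined, 30 gene lists with 1029 members were fixed, of which 940 are named on the array and 847 passed the filter. A list of at least 4 members (28 lists) was described by its median and the percentile of that median among 10000 random lists of the same size, drawn within 20 bins of mean level; a list is said to stand apart below the 1st or above the 99th percentile. The lists overlap, so they are not independent.

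The genes named in the text follow a rule fixed before the data were examined. It takes the 12 largest rises and falls of at least 2-fold in each genotype comparison and in wild-type LSK against MP, leaving out clone names and genes whose probe sets above the filter move in different directions, up to 4 members per list with the largest difference, and a set of fixed names including Fbxw7, Myc and the cyclins. Fewer than these are printed. Named outside the rule, after their values were seen, are Jchain, Met, Tgm2, Meis1, the genes higher or lower in both populations, the plasma cell genes and the genes near Fbxw7.

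Genes enriched in LSK or MP cells were defined as at least 2-fold apart in the mean over both genotypes. Because choosing genes on arrays that enter a comparison shifts that comparison, data with no genotype effect were simulated 20 times and the same choice made in them; this was added after the data were examined. The procedure was tested on simulated data with the noise of the MP comparison over 12239 genes, 200 of them changed: 98% of those shifted by log2 1.5 and 100% of those shifted by 3 passed 2-fold in the right direction, 0.00831% of unchanged genes passed, 2.33% of unchanged lists of 35 genes fell outside the percentile range and 100% of lists shifted by log2 0.3 lay above it. In the MP comparison itself 2.31% of genes passed 2-fold, so the simulated noise gave far fewer large differences than were seen. How many of the differences seen are noise is not known. That simulation also has no animal-to-animal variation in it, so its rates do not give the rate of chance passes between single arrays. The log2 differences between genotypes also spread more in LSK (SD 0.434) than in MP (SD 0.362).

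Alternatives planned before the data were examined were no level filter, a filter at the 75th percentile (an intensity of 606), the mean of all probe sets of a gene, leaving out probe sets marked as shared or cross-reacting, centring each difference on its median or on a lowess curve with a span of 0.3, thresholds of 1.5-fold and 3-fold, the mean in place of the median of a list, and other definitions of enriched genes. Alternatives recomputed percentiles with 2000 random lists. Chosen after the data were examined were the ratio of array spreads with its alternatives, the plasma cell list, and corrections to the naming: control probe sets were left out, and outdated synonyms that are now the symbol of another gene were no longer used to match list members. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.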

Results

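Gene expression was measured on Affymetrix arrays of 45101 probe sets in 4 sorted populations of mouse bone marrow, with 1 array per group. LSK cells lack lineage markers, carry Kit and Sca1, and include the hematopoietic stem cells and multipotent progenitors. MP cells are myeloid progenitors with the same lineage and Kit gate but without Sca1. Each population was sorted from wild-type and from Fbw7-deficient marrow, and the marrow of 3 mice was pooled per genotype before the sort, so the LSK and MP cells of a genotype came from the same animals. Fbw7, encoded by Fbxw7, is the subunit of an SCF ubiquitin ligase that binds substrates such as cyclin E, MYC and Notch for degradation. All animals had received 3 injections of polyI:C at 20 ug per g, a double-stranded RNA mimic that induces interferon, and were sampled 2 weeks later. The median intensity over all probe sets was 156 on the wild-type LSK array, 159 on the Fbw7-deficient LSK array, 157 on the wild-type MP array and 155 on the Fbw7-deficient MP array. No group had a replicate, so the number of arrays limits the precision: every genotype difference lies between single arrays, no error between replicates can be given, no test was made, and percentiles of gene lists describe these arrays and not the genotypes at large.

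Fbxw7 itself read 1355 in wild-type LSK, 1103 in Fbw7-deficient LSK, 691 in wild-type MP and 958 in Fbw7-deficient MP on its brighter probe set, a log2 difference between genotypes of -0.30 in LSK and 0.47 in MP. Its other probe set gave log2 differences of 0.09 and 0.44. The part of the gene that was removed is not given in the sources used here, so it is open whether these probe sets lie inside it, and they do not check the genotype labels. Xist, the RNA of the inactive X chromosome, read 11275, 6771, 7032 and 5456 in the same order of arrays. The Y-linked gene Eif2s3y read 1562, 1031, 1651 and 1384, so both were above the level filter on all 4 arrays. Xist was higher by log2 0.68 in LSK than in MP of the same wild-type pool, so its level does not measure the sex mix of a pool. Whether that mix differed between the genotypes is not known. In RNA quality, the wild-type LSK array stood apart: the ratio of the 3' to the 5' control probe set of Gapdh was 4.30 there, against 2.75 in Fbw7-deficient LSK, 2.60 in wild-type MP and 2.95 in Fbw7-deficient MP. For Actb the ratios were 3.53, 2.89, 2.67 and 2.99.

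The comparison of Fbw7-deficient with wild-type LSK cells addresses how loss of Fbw7 alters the stem cell compartment, whose quiescence is the subject of the study's title. Genes of hematopoietic stem cells, of quiescence and of megakaryocytes were lower in Fbw7-deficient LSK cells, while genes of neutrophils, macrophages and erythroid cells were higher, several of them by more than 4-fold. Genes of ribosome biogenesis and of the mitochondrial respiratory chain were higher by small amounts. Of 12239 genes that passed the level filter, 219 were at least 2-fold higher and 239 at least 2-fold lower in Fbw7-deficient LSK. With the mean of all probe sets these counts were 174 and 133, so the larger count changed side. Where a gene past 2-fold had a further probe set above the filter, that probe set moved the same way in 159 of 167 genes and by 2-fold in 71.

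The stem cell list had a median log2 difference of -0.61 in LSK, with 15 of its 52 measured members at least 2-fold lower, none 2-fold higher and 46 below 0. Mmrn1, which encodes the platelet and endothelial protein multimerin, went from 1604 to 367 (log2 -2.13). Hlf and Mecom, transcription factors of hematopoietic stem cells, went from 5515 to 1677 (log2 -1.72) and from 3043 to 1006 (log2 -1.60). Eya2 had a log2 difference of -1.65. The quiescence regulators had a median of -0.55, with 7 of 36 members 2-fold lower and none 2-fold higher. Among them were Klf6 (log2 -1.81), Txnip, an inhibitor of thioredoxin (log2 -1.63), the receptor tyrosine kinase signalling inhibitor Spry2 (log2 -1.49) and the angiopoietin receptor Tek (log2 -1.41). The megakaryocyte and platelet list had a median of -0.60, with 6 of 27 members 2-fold lower, among them Pf4 (4338 to 1272), Plek (5649 to 1732) and Itga2b (3384 to 1320). Immediate early and stress genes had a median of -0.48, with 4 of 35 members 2-fold lower, including Tnfaip3 (log2 -1.78), although the heat shock genes Hspa1a (log2 2.62) and Hspa1b (log2 1.96) were higher. The medians of these 4 lists lay below those of all 10000 random lists matched on mean level. Some genes stand in more than 1 list, such as Mmrn1 in the stem cell and megakaryocyte lists. Tek is in the stem cell and quiescence lists, and Klf6 in the quiescence and immediate early lists. In the order given, the 4 lists were higher in wild-type LSK than in wild-type MP (medians 1.25, 0.78, 0.39 and 0.57). Their fall thus runs toward MP levels. Admixture of MP cells in the LSK gate is weighed below for the stem cell list and was not tested for the others. The adhesion and homing receptors (median -0.24, 2 of 27 members 2-fold lower, percentile 0.05) and the reported Fbw7 substrates (median -0.24, 2 of 28 members 2-fold higher and 2 lower, percentile 0.09) were also low. The percentile of the substrates was 1.2 with the stricter level filter and 1.4 with the mean of all probe sets, which ends that call. The arrays measure RNA, so the levels of the substrate proteins, on which Fbw7 acts, are not seen in either population. The wild-type LSK array, on which these genes were high, was also the array with the larger 3' to 5' ratio of Gapdh (4.30 against 2.75).

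Among the largest individual differences in the lower direction were Klhl4 (370 to 41.9), the interferon-induced guanylate-binding protein gene Gbp2 (3121 to 485, 6.44-fold), the platelet-derived growth factor receptor gene Pdgfrb (2919 to 598, 4.88-fold) and Bend4 (1378 to 287). Slc35d3, Arhgap6, the purinergic receptor gene P2ry10, the vesicular monoamine transporter gene Slc18a2, Zfp467, the MHC class II gene H2-Ob and the lymphatic growth factor gene Vegfc were lower by log2 values from -2.26 for Slc35d3 to -1.99 for Vegfc.

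The mature neutrophil and macrophage list had a median log2 difference of 0.96 in LSK, with 14 of 29 members at least 2-fold higher and all 29 above 0. The chemokine receptor gene Ccr2 went from 578 to 3476, the beta-glucan receptor gene Clec7a from 419 to 1789, Cd177 from 809 to 3047 and the collagenase gene Mmp8 from 612 to 2223. The neutrophil and monocyte progenitor list had a median of 0.75, with 10 of 30 members 2-fold higher and none 2-fold lower. Elane, which encodes neutrophil elastase, went from 1322 to 9986 (log2 2.92), the coagulation factor gene F13a1 from 1035 to 6073 (log2 2.55), Ms4a3 from 1225 to 6609 (log2 2.43) and Igsf6 from 515 to 2449 (log2 2.25). The erythroid list had a median of 0.88, with 18 of 38 members 2-fold higher and none 2-fold lower. Epb42 and Slc4a1, which encode the red cell membrane proteins 4.2 and band 3, went from 60.7 to 826 and from 1289 to 11215. The Rh blood group genes Rhag and Rhd went from 101 to 855 and from 358 to 2282. All 3 medians lay above those of the 10000 matched random lists. On the wild-type LSK array, where these genes were low, the 3' to 5' ratio of Gapdh was again the larger (4.30 against 2.75).

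Stfa3, a stefin A protease inhibitor gene, was among the 12 largest differences in the higher direction, at 52.4 in wild-type and 1240 in Fbw7-deficient LSK. Its wild-type value lay under the lower quartile of that array (59.9). A value under the level filter of 157, such as this one or that of Klhl4 in Fbw7-deficient LSK, is not shown to be above background, so neither the exact fold nor the rank of such a gene is established; this holds in every comparison. Its relative Stfa2l1 (96.2 to 1063), Apol8 (138 to 1321) and Apol11b (159 to 1119) of the apolipoprotein L family, the metallothionein gene Mt1 (472 to 3346), the sphingomyelin synthase gene Sgms2 (182 to 1279) and the interferon-induced gene Ifi44l (35.7 to 305) were among them too. The immunoglobulin A heavy chain gene Igha went from 221 to 2696 (12.2-fold). The stromal and endothelial list as a whole did not stand apart (median -0.02, percentile 35.5), yet 3 of its 23 members were 2-fold higher and 2 lower. The collagen gene Col1a2 (288 to 1413) and the fibronectin gene Fn1 (644 to 2842) were higher, and Pdgfrb and Tek were lower.

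The ribosome biogenesis and MYC-responsive growth list had a median of 0.34 in LSK, with 46 of 48 members above 0 but none past 2-fold. The largest were Rrp12 (log2 0.79), Nolc1 (log2 0.63), Nop16 (log2 0.62) and Rcc1 (log2 0.61), which act in ribosome assembly, nucleolar organisation and nuclear transport. All 39 measured genes of the mitochondrial respiratory chain were above 0, with a median of 0.25 and none past 2-fold. Cholesterol and fatty acid synthesis genes had a median of 0.26, with Fdps, of the mevalonate pathway, at log2 1.24 and the acetyl-CoA synthetase gene Acss2 at log2 -1.23. These 3 medians lay above all matched random lists, and they too rest on the wild-type LSK array with its larger 3' to 5' ratio of Gapdh (4.30 against 2.75). In wild-type cells, ribosome biogenesis genes (median -0.30, 44 of 48 below 0) and mitochondrial genes (-0.21, 36 of 39 below 0) were lower in LSK than in MP. Their rise in Fbw7-deficient LSK thus runs toward MP levels. Admixture of MP cells in the LSK gate was not tested for these lists. Myc RNA differed little (log2 0.19), and Mycn had a log2 difference of -0.37 on its brightest probe set and 0.02 on the other that passed the filter. Ccne1, which encodes cyclin E1, was 2.03-fold higher (1260 to 2553) on its brighter probe set, which is of a kind marked as cross-reacting. Its other probe set had a log2 difference of 0.80. On the brighter probe set Ccne1 read 3445 in wild-type MP and 6673 in Fbw7-deficient MP, so its rise in LSK also runs toward MP levels. E2f2, a transcription factor of S phase entry, was higher (834 to 2167, log2 1.38). Ccne2 had a log2 difference of 0.38, Ccnd1 of 0.36 (with -0.08 on another of its 3 probe sets), Ccnd2 of 0.03 and Ccnd3 of 0.27 (with -0.67 on another probe set). The kinase inhibitor genes Cdkn1a, Cdkn1b and Cdkn1c had log2 differences of -0.13, -0.51 and -0.67. Kit was at -0.34, Notch1 at 0.21 and Hes1, a Notch target, at 0.26.

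Cell cycle lists did not stand apart in LSK: the median was 0.10 for S phase and DNA replication (percentile 92.8), 0.12 for mitosis (percentile 96.9) and 0.12 for cyclins and cyclin-dependent kinases (percentile 96.3). Mitosis genes still lay mostly above 0, with 33 of 41 members in LSK and 31 of 41 in MP. Their means were 0.18 in LSK and 0.17 in MP. The p53 targets (median -0.15, percentile 1.73), apoptosis regulators (-0.14, percentile 3.74), Notch targets (0.02, percentile 50.5), SCF ligase parts (0.15, percentile 97.7), interferon-stimulated genes (0.01, percentile 61.4), glycolysis genes (0.18, percentile 98.7) and cytosolic ribosomal proteins (-0.01, percentile 12.5) did not either. Among lists of other cell types, the early lymphoid genes (-0.13, percentile 2.53), mast cell, basophil and eosinophil genes (-0.20, percentile 1.05), T and NK cell genes (0.03, percentile 60.2) and dendritic cell genes (-0.03, percentile 31.4) lay within the range. With the stricter level filter the early lymphoid, mast cell and dendritic lists did pass the lower bound (percentiles 0, 0.3 and 0.8). Means over members had the opposite sign to the median for the Notch (-0.10), interferon (-0.09), T and NK cell (-0.16), stromal (0.06) and ribosomal protein (0.01) lists. The B cell genes had a median of 0.18 (percentile 99.8; 2 of 24 members 2-fold higher and 2 lower), with Blnk, a B cell receptor adaptor gene, at 319 and 969, and H2-Ab1 at 1407 and 568. With the stricter level filter that median was 0.02 (percentile 67.5), which ends the call. The single X inactivation gene was at -0.74, and the 3 Y-linked genes had a median of -0.32. In all, 13 of 28 lists stood apart in LSK, where 0.56 would for lists of genes drawn at random. Members of a list can vary together, so the number expected between single arrays is not known.

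**Figure D1:**
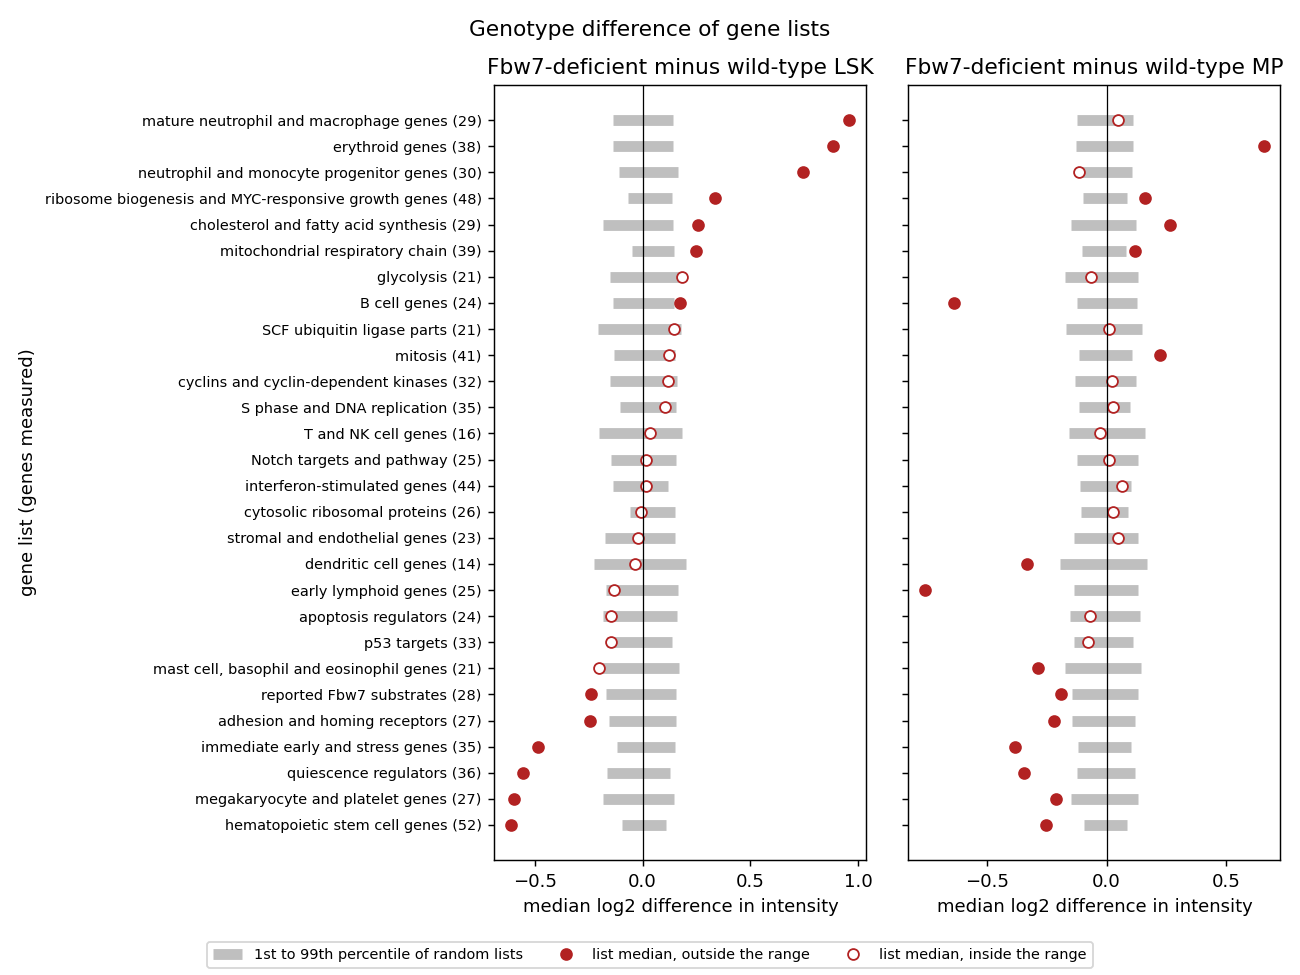
Median log2 difference in intensity between Fbw7-deficient and wild-type cells for each of 28 gene lists, in LSK (left) and MP (right), against the 1st to 99th percentile of matched random lists (grey bars); filled points lie outside that range, and each list's number of measured genes stands in brackets. In LSK the mature neutrophil and macrophage list (0.96) lies farthest to the right and the stem cell list (-0.61) farthest to the left; in MP the erythroid (0.66) and early lymphoid (-0.76) lists do.

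The MP cells served as the control for genes enriched in LSK cells, and the genotype comparison in MP shows which differences are also seen in the sorted MP population. A changed mix of cell types within MP, other cells in its gate and changes within cells cannot be told apart on these arrays. In Fbw7-deficient MP, erythroid genes were higher and genes of early lymphoid, B and dendritic cells were lower, together with quiescence, immediate early and stem cell genes. Genes of neutrophils and macrophages, which were higher in Fbw7-deficient LSK, did not stand apart as lists in MP. There were 101 genes at least 2-fold higher and 182 at least 2-fold lower. Of 125 such genes with a further probe set above the filter, 120 moved the same way on it and 46 by 2-fold.

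The erythroid list had a median of 0.66 in MP, with 8 of 38 members 2-fold higher, none lower and 35 above 0. Slc4a1 went from 2182 to 8481, Epb42 from 197 to 706, Cited4 from 435 to 1491 and Rhag from 792 to 2447. The early lymphoid list had a median of -0.76, with 7 of 25 members 2-fold lower and 22 below 0. Tespa1, of T cell development, had a log2 difference of -1.81, the chromatin organiser Satb1 of -1.31, Dntt, which encodes terminal deoxynucleotidyl transferase, of -1.27 and the cytokine receptor Flt3 of -1.24. The B cell list had a median of -0.64, with 7 of 24 members 2-fold lower; H2-Aa (log2 -1.61), H2-Ab1 (log2 -1.32), the surrogate light chain gene Vpreb1 (log2 -1.30) and the invariant chain gene Cd74 (log2 -1.23) were the largest. The dendritic list (median -0.33, 4 of 14 members 2-fold lower, percentile 0.03) shares H2-Aa, H2-Ab1 and Flt3 with these lists and also holds Irf8. The quiescence regulators (median -0.35, 8 of 36 members 2-fold lower) and immediate early genes (median -0.38, 7 of 35 members 2-fold lower) had Klf6 (log2 -1.52) in common, with Klf2 (log2 -1.27) and Ccng2 (log2 -1.27) in the first and Atf3 (log2 -1.48) in the second. The stem cell list had a median of -0.25, with 6 of 52 members 2-fold lower and 3 higher. The stem and progenitor antigen gene Cd34 went from 6491 to 1103 and Zfp521 from 205 to 51.0, while Clca3a1 went from 235 to 1398.

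The poly-A RNA controls added in labelling had a median log2 difference of -0.60 between the MP arrays and -0.12 between the LSK arrays, whereas the hybridisation controls were at -0.03 in both. A further 4 lists were low in MP: megakaryocyte genes (median -0.21, 4 of 27 members 2-fold lower, percentile 0.06; percentile 3.4 with the stricter level filter), adhesion receptors (-0.22, percentile 0.03), Fbw7 substrates (-0.19, percentile 0.16) and the mast cell, basophil and eosinophil genes (-0.29, percentile 0.01). In the last list 13 of 21 members were below 0, but the eosinophil granule genes Epx (1779 to 4654) and Prg3 (777 to 1902) and the IgE receptor gene Fcer1a (111 to 294) were 2-fold higher, and without a level filter the median was 0.0047 (percentile 49.1). Mitosis genes (median 0.22, 31 of 41 above 0), ribosome biogenesis genes (0.16), cholesterol synthesis genes (0.27) and mitochondrial genes (0.12) were high, with no member of these 4 lists past 2-fold. The neutrophil and monocyte progenitor list (-0.12, percentile 1.65) and the mature list (0.05, percentile 83.7) stayed within the range. In the first, 4 of 30 members were 2-fold lower: the transcription factor genes Irf8 (9804 to 3318) and Cebpa (1416 to 706), the M-CSF receptor gene Csf1r (5624 to 2410) and Ly86 (3245 to 1112).

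Podxl, a sialomucin gene, was 12.5-fold higher in Fbw7-deficient MP (169 to 2117), and Stfa3 went from 45.8 to 737. Trgv4 (67.1 to 545), Plek2 (70.0 to 427), Ifi202b (45.2 to 212) and the cathepsin K gene Ctsk (87.5 to 372) followed. In the lower direction, Igha went from 4238 to 523 (8.10-fold), Sh3d19 from 233 to 37.5, the signalling lymphocyte receptor gene Cd244a from 278 to 54.4, Pdgfrb from 937 to 166, Gpr171 from 880 to 166, the platelet chemokine gene Ppbp from 348 to 77.9 and the heparanase gene Hpse from 1135 to 260. The survival gene Bcl2 was lower (2782 to 864, log2 -1.69), as was the p53 target Pmaip1 (log2 -1.61). Ccne1 had a log2 difference of 0.95 and 1.09 on its 2 probe sets. Ccnd1 was at -1.11, -0.83 and 0.07 on its 3 probe sets, Notch1 at -0.76 and -0.03 on its 2, Kit at -0.64, Mycn at -0.56 (with -0.07 on its other probe set above the filter), Ccne2 at 0.53, Myc at 0.13 and Cdkn1a at -0.37. Ccnd3 was at -0.32, -0.07 and 0.21 on its 3 probe sets. Ccnd2, Cdkn1b, Cdkn1c and Hes1 were between -0.01 and 0.05, with other probe sets of Ccnd2 down to -0.39 and of Cdkn1b at -0.25. Cdkn1c read 101 on both MP arrays, under the level filter, so no lack of change is shown for it. In MP 15 of 28 lists stood apart.

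**Figure D2:**
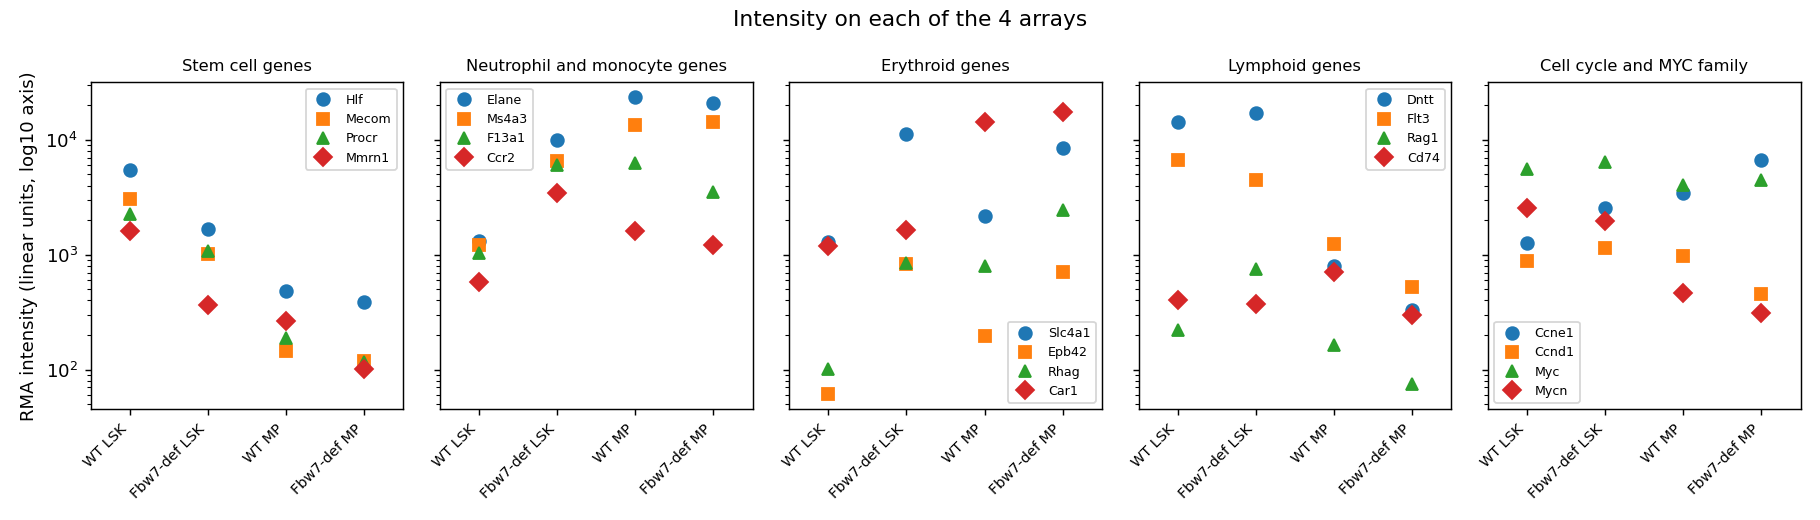
Intensity (linear units on a log10 axis) of selected genes of 5 groups on each of the 4 arrays; each symbol is 1 gene on 1 array, so there are no error bars. Elane lies at 1322 in wild-type LSK and 9986 in Fbw7-deficient LSK and at 23552 and 21158 in the MP populations, and Hlf lies at 5515 in wild-type LSK and 391 in Fbw7-deficient MP.

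Wild-type LSK against wild-type MP gives the genes enriched in the stem cell compartment; the 3' to 5' ratio of Gapdh was 4.30 on the first array and 2.60 on the second, and that of Actb 3.53 and 2.67. Stem cell genes were higher in LSK, with a median of 1.25 and 34 of 52 members at least 2-fold higher, led by Mecom (3043 against 145), Procr, the endothelial protein C receptor (2270 against 187), and Hlf (5515 against 478). Early lymphoid genes (median 0.92, 12 of 25 members 2-fold higher; Dntt 14365 against 794, Flt3 6679 against 1229), quiescence regulators (0.78, 13 of 36) and interferon-stimulated genes (0.55, 10 of 44; Oasl2 956 against 130, Rtp4 2740 against 483) were also higher. Lower in LSK were neutrophil and monocyte progenitor genes (median -1.06, 15 of 30 members 2-fold lower; Elane 1322 against 23552, Ms4a3 1225 against 13381), erythroid genes (-0.90, 18 of 38; the carbonic anhydrase gene Car1 1194 against 14322), mature neutrophil and macrophage genes (-0.69, 6 of 29), mast cell genes (-0.63, 6 of 21; Hdc 1244 against 6879) and ribosome biogenesis genes (-0.30, 1 of 48). In all, 618 genes were 2-fold higher and 294 lower in LSK. Among the largest were Vldlr, the very low density lipoprotein receptor gene (1988 against 55.2), the germ cell helicase gene Ddx4 (1336 against 50.1), Gimap8 (1691 against 86.1) and, in the other direction, Igha (19.2-fold lower). The call of the mast cell list ended without a level filter (percentile 1.15).

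The MP arrays were used to define LSK-enriched genes, at least 2-fold higher in LSK on average over both genotypes. These 475 genes were lower in Fbw7-deficient than in wild-type LSK (median -0.65; 121 were 2-fold lower and 9 higher) and also in MP (median -0.51; 85 lower and 3 higher). The 189 MP-enriched genes were higher in both populations, by a median of 0.76 in LSK and 0.60 in MP. All 4 medians lay beyond those of the 10000 matched random lists. The wild-type LSK array enters both the choice and the LSK comparison, and its 3' to 5' ratio of Gapdh was larger (4.30 against 2.75 in Fbw7-deficient LSK). When the sets were chosen on the wild-type arrays alone, which enter the comparison too, the LSK-enriched genes gave -0.72 in LSK and -0.28 in MP, and simulated data with no genotype effect gave -0.23 and 0.23 for the same choice. For the MP-enriched genes that choice gave 0.87 in LSK and 0.13 in MP, against 0.30 and -0.30 in the simulated data. Simulated medians for the choice over both genotypes lay between -0.01 and 0.003. The simulation counted the whole LSK genotype difference as noise and used that noise for MP too, so its shifts may be too large.

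Fbw7-deficient LSK against Fbw7-deficient MP had 473 genes 2-fold higher and 200 lower. Stem cell genes (median 0.92, 25 of 52 members 2-fold higher), early lymphoid genes (1.35, 16 of 25; Dntt 17155 against 329) and B cell genes (0.29, 7 of 24) were higher in LSK, and erythroid genes were lower (-0.76, 15 of 38). The mature neutrophil and macrophage genes were higher in Fbw7-deficient LSK than in Fbw7-deficient MP (median 0.25, 21 of 29 above 0, percentile 99.9), opposite in sign to the wild-type median of -0.69. The neutrophil and monocyte progenitor genes differed by -0.14, against -1.06 in wild type. Without the probe sets marked as shared or cross-reacting, the B cell median was 0.09 (percentile 85.7), which ends that call.

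Genotype differences in LSK and MP were related across the 12239 genes (Pearson r 0.442, Spearman rho 0.391), which use no array in common but the same pools of mice, and genes are not independent replicates. Of the genes past 2-fold, 46 were higher in both populations, where independent lists would share 1.81, and 55 were lower in both, against 3.55. Shared and higher were Stfa3, Stfa2l1, Apol8, Slc4a1, Epb42, Rhag, Podxl and Mt1. Shared and lower were Pdgfrb, Gbp2, H2-Ob, Mmrn1, Klf6, Klf2, Txnip, Meis1 and Tnfaip3. There were 6 genes higher in LSK and lower in MP (3.26 for independent lists), namely Blnk, Igha, Jchain, Ly86, Met and Rag1. Tgm2 alone was lower in LSK and higher in MP (1.97 for independent lists).

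The difference of the genotype differences, LSK minus MP, was at least 2-fold positive in 269 genes and negative in 162. It includes the wild-type LSK array, whose 3' to 5' ratios were the highest (Gapdh 4.30 against 2.60 to 2.95, Actb 3.53 against 2.67 to 2.99). It was largest for neutrophil and macrophage genes: the mature list had a median of 1.04 with 16 of 29 members past 2-fold, and the progenitor list 0.99 with 15 of 30. B cell genes (0.69, 11 of 24), early lymphoid genes (0.39), glycolysis genes (0.27), dendritic genes (0.23) and ribosome biogenesis genes (0.16) were also more positive in LSK. Stem cell genes (-0.33, 9 of 52 members 2-fold negative and 2 positive), megakaryocyte genes (-0.23) and interferon-stimulated genes (-0.21) were more negative. The erythroid list did not stand apart (0.13, percentile 98.9), nor did the quiescence list (-0.03, percentile 36.2) or the mitosis list (-0.01, percentile 29.3). The megakaryocyte call ended without a level filter (-0.06, percentile 16.1) and the dendritic call with the stricter filter (0.22, percentile 96.8).

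**Figure D3:**
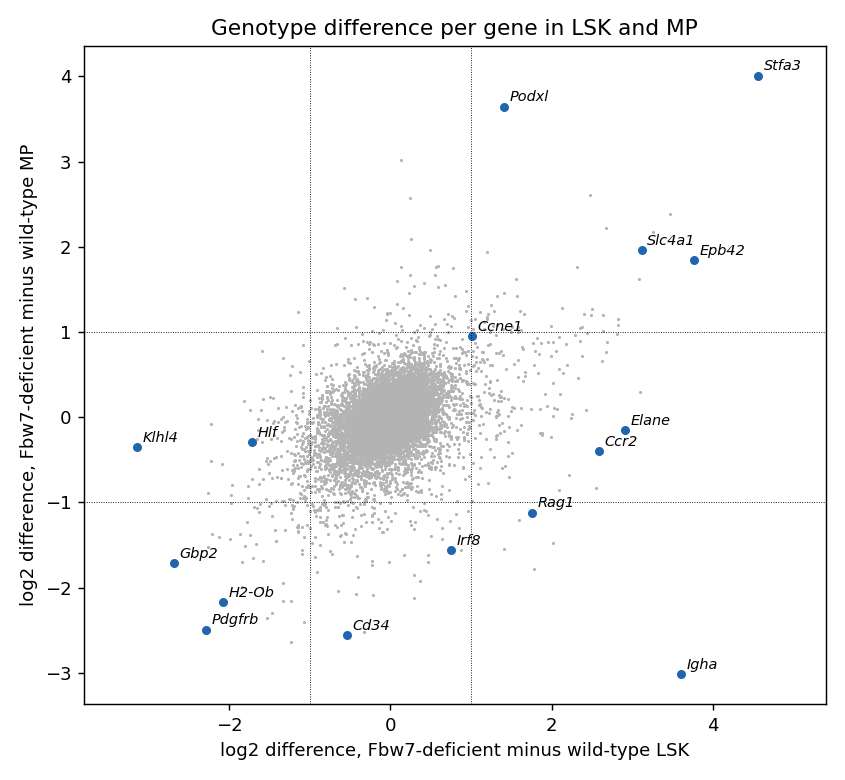
Log2 difference between Fbw7-deficient and wild-type cells in MP (vertical) against that in LSK (horizontal) for each of 12239 genes, 1 point per gene, with dotted lines at 2-fold and named genes in blue. Stfa3 and Slc4a1 lie high in both populations and Pdgfrb and H2-Ob low in both, Elane is at 2.92 in LSK and -0.15 in MP, and Igha is at 3.61 in LSK and -3.02 in MP.

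Pairs of arrays were set against each other by the SD of log2 differences over the same genes. It was 0.362 between the MP arrays, 0.434 between the LSK arrays, 0.582 between the wild-type populations and 0.514 between the Fbw7-deficient ones. Fbw7-deficient LSK and wild-type MP differed by 0.407, less than the LSK arrays did from each other; the latter pair holds the wild-type LSK array, with the highest 3' to 5' ratio of Gapdh (4.30, against 2.60 to 2.95 on the others). Wild-type LSK and Fbw7-deficient MP were farthest apart, at 0.759.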

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

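Of the tests below, those of the mature neutrophil and macrophage list in Fbw7-deficient LSK against MP and of the plasma cell genes were chosen after their results were seen; the share of the 7 neutrophil and monocyte progenitor genes was not set out before either, and the other tests were. No difference was given a p-value, since no group has a replicate.

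Some results had opposite signs in LSK and MP; each such difference rests on 4 arrays and was not tested. Blnk had a log2 genotype difference of 1.60 in LSK and -1.21 in MP, Ly86 of 1.41 and -1.55, Rag1 of 1.76 and -1.12, and Igha of 3.61 and -3.02. The B cell list stood apart in both populations, with a median of 0.18 in LSK and -0.64 in MP, though the LSK median was 0.02 with the stricter level filter.

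Fbw7-deficient LSK cells had more myeloid and erythroid RNA and less stem cell RNA than wild-type LSK cells. The mature neutrophil and macrophage genes were higher in Fbw7-deficient LSK than in Fbw7-deficient MP (median log2 difference 0.25, SD of random list medians 0.059). Cells with the profile of the sorted MP population in the gate, as the whole cause for these genes, would not give this if the arrays held no error. That SD is a spread over genes and not an error between arrays or sorts. The values thus argue against that cause without excluding it, and a subset of MP cells richer in these genes stays open. For the rest, admixture of Sca1-negative progenitors stays open. For list members 4-fold apart, a share of Fbw7-deficient MP RNA was computed. Mixed with wild-type LSK RNA, that share would give the Fbw7-deficient LSK value. It had a median of 0.423 (bootstrap interval over genes 0.414 to 0.562) over 7 neutrophil and monocyte progenitor genes. None of these shares was above 1, and that list had an LSK minus MP median of -0.14. Over 20 stem cell genes the median share was 0.569 (0.456 to 0.692). Its interquartile span was 0.259, under the preset bound of 0.3, though Hmga2 would need -0.438. Over 17 erythroid genes the median share was 0.305 (0.189 to 0.465). Slc4a1 (1.38) and Epb42 (1.19) would need more than 1, and Car1 (0.027), Cited4 (0.039), Mt2 (0.046) and Epor (0.079) little. The preset prediction for the erythroid genes asked for shares between 0 and 1 and for an interval overlapping that of the stem cell genes. It was met only in part, since 2 shares were above 1 and the intervals overlap only from 0.456 to 0.465. The genes were picked on arrays that enter the shares. All intervals of the shares are bootstrap intervals over genes, which are not replicates, so they give no error between arrays or sorts. Against the stronger 3' bias of the wild-type LSK RNA as the whole cause, the least-moving probe set of 30 myeloid and erythroid genes had a median change of 0.253, above the 0.171 of the 3' Gapdh control, but by only slightly more than the SD of 0.070. Open and untested are other cells in the gate, an altered Sca1 level, a changed mix of cell types within LSK, and the genotype itself.

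In both populations, 101 genes were 2-fold apart in the same direction. Sequence inherited beside the targeted gene may account for few of them, since 3 of the 101 (Lmna, Sh3d19 and Txnip, 2.97%) lie among the 200 tested genes nearest to Fbxw7, against 1.64% of all tested genes. Strain differences elsewhere cannot be told apart from genotype: 9 pairs of these genes lay within 10 tested genes of each other, against a median of 8 in random draws (percentile 65), and the labels give no strain. The shared pool of 3 mice per genotype also stays open, since neither population samples other animals, as does the genotype.

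Igha was higher in LSK and lower in MP in the Fbw7-deficient pool. Plasma cells are a candidate source: 15 other plasma cell genes, a list written after Igha was seen, had a median of 0.446 in LSK (percentile 100) and -0.22 in MP (percentile 0.365). Of the abundant plasma cell transcripts, Jchain went from 211 to 725 in LSK and from 435 to 126 in MP, and Ighm from 7738 to 10545 and from 5850 to 2718, though the probe sets of Ighm differ in direction in MP. Not all of the list followed Igha: Fkbp11 was higher in both (log2 1.77 and 0.88), Derl3, Sdf2l1 and Xbp1 were above 0 in MP, and Herpud1 was below 0 in LSK; Xbp1 and Hsp90b1 are abundant on all 4 arrays, Ighm, Irf4 and Pou2af1 also stand in the B cell or early lymphoid lists, and the lineage and Kit gates should remove plasma cells. Part of the list was also lower in wild-type LSK than in wild-type MP, such as Fkbp11 (log2 -1.74) and Sdf2l1 (log2 -1.70), though Ighm, Sdc1 and Herpud1 were not. MP-enriched genes in general were higher in Fbw7-deficient than in wild-type LSK (median 0.76). The LSK median of the list thus does not by itself point to plasma cells. A difference between the pools of 3 mice and the genotype stay open and were not tested.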

How the results depend on the processing

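The alternatives for the ratio of array spreads were chosen after the result was seen; the others were planned. No paired analysis was possible between genotypes, because no pool of mice holds both and all arrays carry the same replicate number. LSK and MP cells do share a pool, and the report compares them within each; a paired fit of LSK against MP over both pools, with 1 residual degree of freedom, could have been made but was not run. With 1 array per group no array could be left out, the wild-type LSK array with its higher 3' to 5' ratio included. Array values have a background that compresses differences of dim genes, so small differences of genes near the level filter may be understated; omitting the filter moved the stem cell median in LSK to -0.55. A list median is said to move when it changes by more than the SD of matched random list medians, a count when it changes by more than 1.5 times, a correlation by more than 0.05 and the ratio of spreads by more than 0.1. Where values moved, the cause was not tested unless it is stated.

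The correlation of genotype differences between LSK and MP stayed between 0.408 and 0.478. The SD between Fbw7-deficient LSK and wild-type MP was 0.938 of that between the LSK arrays, and from 0.858 to 0.942 under the alternatives. Of 801 values of named genes none moved with lowess centring. With the mean of all probe sets 136 moved and 632 did not, and the others had no value because the gene fell below the level filter.

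Other thresholds change counts by construction. At 1.5-fold, 551 genes were higher and 867 lower in Fbw7-deficient LSK, and 364 and 644 in Fbw7-deficient MP. Wild-type LSK against MP had 1553 higher and 846 lower, Fbw7-deficient LSK against MP 1177 and 580, and the difference of genotype differences 695 and 670. At 3-fold, the counts in the same order were 83 and 43, 23 and 37, 188 and 115, 170 and 77, and 82 and 27. In LSK the lower genes thus outnumbered the higher at 1.5-fold and 2-fold but not at 3-fold. That order at 2-fold depended on other settings too: with the mean of all probe sets 174 genes were higher and 133 lower, 126 of these among the 239 of the report, and with the stricter filter 167 were higher and 165 lower. There were 67 higher and 104 lower in Fbw7-deficient MP (101 and 182 in the report), 386 higher in wild-type LSK against MP (618) and 89 negative in the difference of genotype differences (162). The stricter filter, which tests fewer genes, also left 89 negative there. Other counts stayed within 1.5 times.

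The enriched genes kept their directions under every alternative. Chosen on the wild-type arrays alone, LSK-enriched genes had medians of -0.72 in LSK and -0.28 in MP, and MP-enriched genes of 0.87 and 0.13. Chosen on the Fbw7-deficient arrays alone, they had -0.45 and -0.64, and 0.24 and 0.68. Choosing on an array of the comparison shifts it by construction. With the stricter filter LSK-enriched genes were at -0.68 and -0.55 and MP-enriched genes at 0.88 in LSK. With the mean of probe sets LSK-enriched genes were at -0.61 in LSK. Without shared probe sets MP-enriched genes were at 0.80 in LSK and 0.57 in MP. Lowess centring gave -0.63 and 0.79 in LSK.

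Of 67 calls of lists standing apart over the 5 comparisons, 62 held without a level filter, 61 with the stricter filter, 63 with the mean of probe sets, 65 without shared probe sets, 67 with median centring and 65 with lowess centring. A single called median changed sign: mast cell, basophil and eosinophil genes in MP, at 0.0047 without a level filter. Beyond the calls named in the report, these ended. For wild-type LSK against MP they were adhesion genes without a filter (percentile 84.1), with the stricter filter (92.8) and with lowess centring (98.4), B cell genes with the stricter filter (32.6) and mitochondrial genes with the mean of probe sets (1.33). For Fbw7-deficient LSK against MP they were mast cell genes without a filter (2.45), ribosome biogenesis genes (2) and mitochondrial genes (1.18) with the mean of probe sets, and mitochondrial genes without shared probe sets (5.65). Lowess centring also ended the dendritic call in the difference of genotype differences (98.8).

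Lists that did not stand apart in the report did so under some alternatives. In LSK these were glycolysis genes without a filter (percentile 99.7), with the mean of probe sets (99.4) and, only just, with median centring, early lymphoid genes without a filter (0.1) and without shared probe sets (0.8), and mast cell genes with the mean of probe sets (0.35) and without shared probe sets (0.75). In MP they were p53 targets with the stricter filter (0.25), interferon genes with the mean of probe sets (99.2) and stromal genes with that mean (99.7) and without shared probe sets (100). For Fbw7-deficient LSK against MP they were substrates (99.6) and T and NK cell genes (100) without a filter, and p53 targets (99.95) and Notch genes (99.9) with the stricter filter, where Notch genes also did for wild type (99.8). In the difference of genotype differences they were T and NK cell genes without a filter (99.9) and erythroid genes with the mean of probe sets (99.5) and without shared probe sets (99.9).

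Of 140 list medians, 58 moved on averaging over members, 52 without shared probe sets, 45 with the stricter filter, 36 with the mean of probe sets, 7 with lowess centring and none with median centring; 25 moved and 1 reversed without a filter. Their values follow by comparison, with the lists named in short.

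In the LSK genotype comparison, averaging over members gave -0.069 for apoptosis, -0.10 for Notch, -0.092 for interferon, 0.89 for neutrophil progenitor, 1.10 for mature neutrophil, 0.99 for erythroid, -0.11 for mast cell and -0.16 for T and NK genes. It also gave 0.064 for stromal and -0.37 for immediate early genes. Omitting the level filter gave -0.55 for stem cell, 0.87 for mature neutrophil, 0.80 for erythroid, -0.38 for megakaryocyte, -0.0012 for mast cell and -0.15 for adhesion genes. Applying the stricter filter gave -0.29 for Notch, -0.091 for interferon, 1.39 for mature neutrophil, 0.97 for erythroid, -0.30 for mast cell, -0.43 for early lymphoid, 0.018 for B cell and -0.36 for dendritic genes. It also gave -0.57 for immediate early genes. Averaging a gene's probe sets gave 0.17 for S phase, -0.56 for stem cell, -0.41 for quiescence, -0.11 for substrates, 0.59 for neutrophil progenitor, 0.87 for mature neutrophil and 0.71 for erythroid genes. Omitting shared probe sets gave 0.17 for S phase, 0.40 for ribosome biogenesis, -0.37 for substrates, 1.06 for mature neutrophil, -0.045 for glycolysis, 0.32 for mitochondrial and 0.056 for ribosomal protein genes. Centring on a lowess curve gave -0.064 for ribosomal protein genes.

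In the MP genotype comparison, averaging over members gave 0.17 for mitosis, -0.19 for p53, -0.14 for apoptosis, -0.28 for neutrophil progenitor, 0.72 for erythroid, -0.35 for megakaryocyte, -0.075 for mast cell and -0.64 for early lymphoid genes. It also gave -0.48 for dendritic and -0.35 for adhesion genes. Omitting the level filter gave -0.21 for stem cell, -0.11 for megakaryocyte, 0.0047 for mast cell, -0.64 for early lymphoid, -0.58 for B cell and -0.15 for dendritic genes. Applying the stricter filter gave -0.33 for stem cell, -0.25 for p53, -0.17 for Notch, 0.081 for SCF, -0.58 for mast cell, -1.21 for B cell, -0.95 for dendritic and 0.20 for stromal genes. Averaging a gene's probe sets gave 0.12 for mitosis, -0.16 for stem cell, -0.15 for quiescence, -0.51 for early lymphoid, -0.56 for B cell, 0.16 for stromal, 0.21 for cholesterol and -0.33 for adhesion genes. Omitting shared probe sets gave -0.050 for S phase, 0.14 for mitosis, -0.21 for stem cell, -0.24 for quiescence, 0.12 for mature neutrophil, 0.74 for erythroid, -0.54 for B cell and 0.26 for stromal genes.

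For wild-type LSK against MP, averaging over members gave 1.43 for stem cell, 0.25 for p53, 0.32 for Notch, 0.64 for interferon, -1.33 for neutrophil progenitor, -1.17 for erythroid, 1.04 for early lymphoid and 0.28 for T and NK genes. It also gave 0.21 for dendritic and 0.46 for adhesion genes. Omitting the level filter gave 1.09 for stem cell, -0.17 for mast cell, -0.043 for dendritic and 0.033 for adhesion genes. Applying the stricter filter gave 0.91 for quiescence, 0.21 for p53, 0.52 for Notch, 0.64 for megakaryocyte, 1.30 for early lymphoid, -0.0035 for B cell, -0.30 for T and NK and 0.28 for dendritic genes. Averaging a gene's probe sets gave 1.07 for stem cell, 0.48 for quiescence, 0.081 for apoptosis, -0.77 for mast cell, 0.10 for T and NK, 0.65 for immediate early and 0.15 for cholesterol genes. Omitting shared probe sets gave -0.37 for ribosome biogenesis, 1.39 for stem cell, 0.48 for substrates, -1.18 for neutrophil progenitor, -1.18 for erythroid, 1.12 for early lymphoid, 0.10 for T and NK and -0.13 for dendritic genes. It also gave -0.21 for stromal, 0.46 for immediate early and -0.28 for mitochondrial genes. Centring on a lowess curve gave 0.094 for ribosomal protein genes.

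For Fbw7-deficient LSK against MP, averaging over members gave 0.10 for mitosis, 1.03 for stem cell, 0.67 for quiescence, 0.31 for p53, 0.22 for apoptosis, 0.26 for Notch, 0.32 for substrates and -0.89 for erythroid genes. It also gave -0.64 for mast cell, 1.53 for early lymphoid, 0.61 for B cell, 0.68 for dendritic, 0.61 for immediate early and 0.59 for adhesion genes. Omitting the level filter gave 0.62 for stem cell, 0.043 for Notch, -0.70 for erythroid, -0.12 for mast cell, 0.23 for dendritic, 0.43 for immediate early and 0.28 for adhesion genes. Applying the stricter filter gave 1.09 for stem cell, 0.66 for quiescence, 0.45 for p53, 0.45 for Notch, 0.51 for mature neutrophil, -0.82 for erythroid, -0.56 for mast cell and 1.67 for early lymphoid genes. It also gave 0.77 for B cell, -0.18 for T and NK, 0.88 for dendritic and 0.062 for stromal genes. Averaging a gene's probe sets gave 0.68 for stem cell, 0.34 for quiescence, -0.21 for neutrophil progenitor, -0.64 for erythroid, 1.23 for early lymphoid and 0.27 for T and NK genes. Omitting shared probe sets gave 1.02 for stem cell, 0.66 for quiescence, 0.045 for Notch, -0.23 for neutrophil progenitor, -0.85 for erythroid, -0.56 for mast cell, 0.088 for B cell and -0.18 for stromal genes. It also gave 0.35 for immediate early, 0.016 for glycolysis and -0.054 for mitochondrial genes.

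For the difference of genotype differences, averaging over members gave -0.41 for stem cell, -0.17 for quiescence, 0.062 for p53, -0.058 for Notch, -0.12 for interferon, 1.17 for neutrophil progenitor, 0.28 for erythroid and 0.50 for early lymphoid genes. It also gave 0.89 for B cell, -0.077 for T and NK, 0.47 for dendritic, 0.14 for mitochondrial, 0.13 for adhesion and 0.047 for cyclin genes. Omitting the level filter gave 0.030 for p53, -0.057 for megakaryocyte and 0.10 for adhesion genes. Applying the stricter filter gave -0.27 for stem cell, -0.13 for Notch, 0.051 for substrates, 1.24 for mature neutrophil, -0.57 for megakaryocyte, 0.27 for early lymphoid, 0.016 for T and NK and -0.14 for stromal genes. Averaging a gene's probe sets gave 0.052 for mitosis, 0.20 for ribosome biogenesis, -0.11 for interferon, -0.30 for megakaryocyte, 0.064 for T and NK, -0.15 for stromal, -0.037 for immediate early and 0.14 for adhesion genes. Omitting shared probe sets gave 0.17 for S phase, 0.042 for mitosis, 0.26 for ribosome biogenesis, -0.24 for stem cell, 0.066 for p53, -0.048 for Notch, -0.10 for substrates and 1.13 for neutrophil progenitor genes. It also gave 1.10 for mature neutrophil, 0.23 for erythroid, -0.31 for megakaryocyte, 0.46 for dendritic, -0.19 for stromal, 0.36 for glycolysis and 0.19 for mitochondrial genes. Centring on a lowess curve gave 0.11 for ribosome biogenesis, 0.91 for neutrophil progenitor, 0.21 for glycolysis, 0.026 for mitochondrial and -0.093 for ribosomal protein genes.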

Other observations

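The genes below were chosen after their values were seen, and no explanation of them was tested. Among the genes 2-fold higher in both populations were the iron exporter gene Slc40a1, with log2 differences of 1.62 in LSK and 1.03 in MP, the biliverdin reductase gene Blvrb (1.33 and 1.08), the asparagine synthetase gene Asns (1.66 and 1.21) and the cathepsin E gene Ctse (2.49 and 1.20). Among those lower in both were the angiopoietin gene Angpt1 (-1.03 and -1.04), the regulators of G protein signalling Rgs1 (-1.43 and -1.32) and Rgs18 (-1.22 and -1.19), and the NF-kappa-B inhibitor gene Nfkbiz (-1.10 and -1.29). The stem cell list was not uniform: Hmga2 went from 4622 to 6439 in LSK (log2 0.48) and had a log2 difference of -0.60 in MP.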
